A study of Bactrocera dorsalis with 4 samples.

How the data were processed

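Small RNA was measured in whole bodies of the oriental fruit fly, Bactrocera dorsalis, at 4 developmental stages. Each stage is 1 library from 1 pool, which per the labels held about 2000 eggs, or 10 larvae, or 10 pupae, or 8 adults. Per the labels, RNA of 18 to 30 bases was taken from a gel, joined to adaptors at both ends, reverse transcribed and amplified by PCR, and the libraries were sequenced on an Illumina (Solexa) machine. The trimming, the reference set of miRNA names, the mismatches allowed, the aligner and any genome build are not given in the sources used here. No genome or miRNA annotation was used here, so miRNAs are named as the deposited table names them and have no coordinates.

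The authors deposited 1 table with a list per library, giving a miRNA name, a read count, a normalized value and a sequence. The counts are whole numbers of reads per name, per the file headers. The authors' normalized values are RPM: each equals its count times 1 factor per library, to within 0.0001621 RPM. That factor gives library totals of 7720770 reads in egg, 7665826 in larva, 7693140 in pupa and 7605808 in adult. The listed reads sum to 479166 in egg, 3350255 in larva, 3030216 in pupa and 2293920 in adult, so the table holds part of each library. The lists held 2385 different names, of which 1360 were in 1 library, 446 in 2, 285 in 3 and 294 in all 4. The lowest listed count is 1 read. A name absent from a library's list was taken as 0 reads there, which the table itself does not state.

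Names are not independent measurements. In egg 96, in larva 143, in pupa 128 and in adult 126 sequences lay inside another listed sequence or held one, and they carried 4.99%, 21.7%, 18.5% and 25.1% of the listed reads. Names such as miR-184 and miR-184-3p can therefore hold the same reads, and sums can count a read more than once. A name could also stand for different sequences in different libraries. After this was seen in the data, the sequences of each name were checked for a shared run of 16 bases. Close variants can lack such a run, so its absence does not show that sequences are unrelated.

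With 1 library per stage no test between stages was possible and no p-value is given. The rule for calls, the lists, the rule for named miRNAs and the first set of alternatives were fixed before the data were examined. Pairs of stages were compared by the ratio of a name's share of the listed reads. Its exact 95% interval came from the conditional binomial distribution (Clopper-Pearson). A name was called higher or lower when the ratio was at least 2 either way, the interval excluded 1 and at least 1 of the 2 libraries had 10 or more reads. A count of 0 was set to 3 reads per library. That floor is 0.389 RPM of the library in egg, 0.391 in larva, 0.390 in pupa and 0.394 in adult. A ratio with this floor is a nominal bound, given below as "at least", and only where the other library's share lies above the floor. It is not a 95% limit, because the lower limit of the exact interval is smaller. For miR-222-5p, at least 9816-fold higher in larva than in egg, that limit is 7983. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A call compares 2 libraries and not the stages they came from.

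The names reported are the 10 most abundant of each library, the 10 largest ratios each way between successive stages among called names with 100 or more reads in 1 of the 2 libraries, and the detected members of 12 lists. Where copies of a miRNA were listed, the copy with the most reads stood for them. The lists, from Drosophila biology, were the miR-309 cluster, the let-7 complex, the miR-34 cluster, muscle, nervous system, growth and fat metabolism, the K-box family, Hox clusters, the miR-92 family, ovary, testis and midgut. Counts of members use all names of a member added together, while the folds given for single miRNAs are of 1 name. A list's median log2 ratio covers all members listed in either library, including those below the minimum of reads, which are in no count of higher, lower or neither. For such members the floor can turn the direction. With 0 egg reads and 2 larva reads, miR-iab-8 enters as 10.5-fold lower in larva. The median was placed among 10000 random lists of the same size, as a description of these libraries. Each draw came from the member itself and the 25 names on each side of it in abundance. At the ends of the abundance ranking, as for the most abundant miRNAs, these names were not evenly placed around the member. Plant and vertebrate miRNA names were fixed as markers of other organisms. Spearman's rho between libraries was given with the 95% range of 500 bootstrap resamples of names. The dominant arm of a precursor was compared where every library had 10 or more reads of it, by exact intervals on opposite sides of an equal share.

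Each comparison was recomputed under 8 alternatives chosen beforehand and 4 chosen after seeing the data. The first were median-of-ratios size factors from DESeq2, TMM factors from edgeR, the total without the 5 most abundant names, no minimum of reads, a minimum of 100 reads, a ratio of at least 4, names added per miRNA, and the authors' normalized values, which scale by the library total. The 4 later ones kept only names with matching sequences, grouped names by shared runs, kept the name with the most reads per miRNA, or left out names with tRNA, rRNA or vertebrate sequence. Lists were also recomputed without members unlisted in 1 library, with 1 name per member and, chosen after seeing the data, with matching sequences and with library totals. Names seen in 1 stage alone were recounted with minimums of 3 and 100 reads and with counts thinned to 479166 reads.

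The tRNA and rRNA sequences were written from general knowledge and not taken from a reference of this fly, and a name was assigned to them by a shared run of 12 bases. This way of assigning, its run length and part of the sequences were chosen after a looser pattern of the conserved tRNA boxes had given a weak result. A sequence was taken as vertebrate when it began with the first 18 bases of a vertebrate miRNA, also written from general knowledge, or the first 20 for let-7c, which shares 18 with the fly's let-7.

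The calling rule was tested on simulated data. Counts were drawn at random around those of the earlier library, scaled to the depth of the later one, with 100 names changed 3-fold and 100 changed 6-fold, up or down. Of the 3-fold changes 97% were called in the right direction for larva versus egg, 94% for pupa versus larva and 92% for adult versus pupa. Of the 6-fold changes 99%, 96% and 95% were. Among 522, 461 and 365 unchanged names, 2, 5 and 0 were called. The simulation had counting error only and used the known depth, so it says nothing about variation between pools. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.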

Results

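Small RNA profiles were obtained from 1 library each of eggs, larvae, pupae and adults of the oriental fruit fly, to compare the stages of its life cycle. The libraries held between 7605808 and 7720770 reads. Reads listed under a miRNA name made up 6.21% of the egg library (95% Clopper-Pearson interval 6.19 to 6.22), 43.7% of larva (43.67 to 43.74), 39.4% of pupa (39.35 to 39.42) and 30.2% of adult (30.13 to 30.19). These sums can count a read more than once, which the intervals do not cover. Counting only the largest name of each group joined by shared runs kept 97.6% of listed reads in egg. In larva, pupa and adult it kept 88.1%, 89.5% and 86.25%, so the listed shares are upper values. The lists held 1156 names in egg, 1116 in larva, 924 in pupa and 1087 in adult. There were no replicates, so the intervals below are of counting error only.

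Because the listed share differed, each ratio depends on its denominator. Ratios are of shares of the listed reads unless the library total is named. By library total every larva-to-egg ratio is 7.04 times as large (2.82 on the log2 scale), every pupa-to-egg ratio 6.35 times and every adult-to-egg ratio 4.86 times. Between the later stages the shift is -0.15 on the log2 scale for pupa versus larva, -0.39 for adult versus pupa and -0.54 for adult versus larva. Levels in RPM are of the library total.

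The leading names were an early-embryo miRNA in egg and a muscle miRNA in larva and adult. In egg miR-5-5p, a member of the miR-309 cluster, held 17.0% of listed reads (16.91 to 17.12). The muscle miRNA miR-1-3p (TGGAATGTAAAGAAGTATGGAG) held 38.5% in larva (38.47 to 38.57) and 32.8% in adult (32.73 to 32.86). It was at 65.7 RPM in egg, 168400 in larva, 73560 in pupa and 98910 in adult. In pupa miR-4175-3p led with 30.3% (30.24 to 30.35), and its sequence shares a run of 12 bases with a tRNA. The miRNA miR-184-3p (TGGACGGAGAACTGATAAGGGC), which acts in oogenesis and the early embryo of Drosophila, was at 94.2 RPM in egg, 19170 in larva, 14840 in pupa and 15280 in adult. The members of the 12 lists held 21.6% of listed reads in egg, 50.1% in larva, 27.4% in pupa and 43.8% in adult, counting 1 name per miRNA.

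The 10 most abundant names held 57.7% of listed reads in egg, 74.9% in larva, 69.7% in pupa and 65.3% in adult. After miR-5-5p, those of egg were miR-5394-5p, miR-1683, miR-3340, miR-4175-3p, miR-222b-5p, miR-357, miR-6656-5p, miR-200b-3p and miR-6-3p. Of these, miR-5394-5p (50671 reads), miR-1683 (39452), miR-6656-5p (11858) and miR-200b-3p (7221) were listed in egg alone, and miR-3340 had no shared run with its sequence in the other stages. In larva miR-1-3p was followed by miR-4175-3p, miR-222-5p, miR-184-3p, miR-184, miR-6706-5p, miR-275, miR-275-3p, miR-2197 and miR-2854. In pupa miR-4175-3p and miR-1-3p were followed by miR-184-3p, miR-184, miR-4419b, miR-2854, miR-275, miR-275-3p, miR-2197 and miR-2522b-5p. In adult miR-1-3p was followed by miR-4175-3p, miR-184-3p, miR-184, miR-765, miR-6127, let-7-5p, let-7, miR-276a-3p and miR-276-3p. Names with nested sequences, such as miR-275 and miR-275-3p, can hold the same reads.

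**Figure D1:**
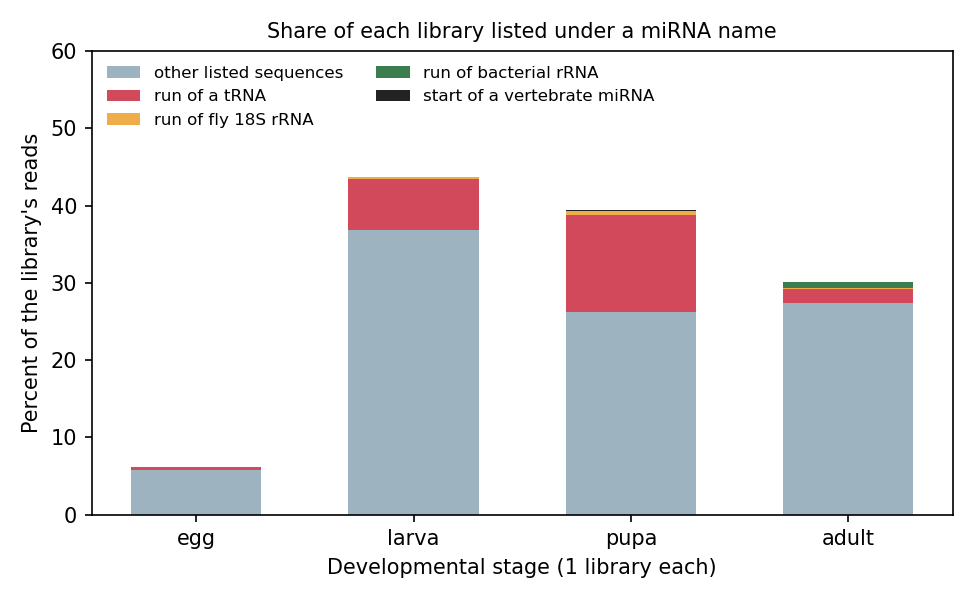
Percent of each library's reads listed under a miRNA name, 1 stacked bar per stage, split by whether the sequence shares a run of 12 bases with a tRNA, fly 18S rRNA or bacterial rRNA, or begins as a vertebrate miRNA. The whole bar is 6.21% in egg and 43.7% in larva, and in pupa the tRNA part is 31.7% of the listed reads. Reads held by nested names can be counted more than once.

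Larva and egg, the first pair of successive stages, differed in early-embryo and growth miRNAs and in miR-1. All 5 detected members of the miR-309 cluster, which acts in clearing maternal mRNA from the Drosophila embryo, were lower in larva. The muscle miRNA miR-1-3p was 364-fold higher in larva (334 to 398), or 2564-fold by library total. Of 7 members of the growth and fat metabolism list, 5 were higher in larva, 1 was lower and 1 was neither. All 3 members of the miR-34 cluster, linked to ageing in adult Drosophila, were higher. The members called higher or lower kept that call by library total, except that bantam, lower by the sum of its names, was not called, and the growth member that was neither, miR-278, was higher.

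In the miR-309 cluster, miR-5-5p (AAAGGAACGTTCGTTGTGATAT in both) was at 10560 RPM in egg (10490 to 10630) and 49.2 in larva (44.3 to 54.4). It was 1512-fold lower in larva (1366 to 1677), or 215-fold by library total. Next, miR-6-3p was 2871-fold lower (1710 to 5255), miR-286-3p 2143-fold (1127 to 4692), miR-4-3p 754-fold (420 to 1514) and miR-309-3p 182-fold, from 52 reads to 2 (47.9 to 1541). By library total these were 408-fold, 304-fold, 107-fold and 25.8-fold lower. The list's median log2 ratio was -9.56, at percentile 0.5 of random lists.

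In the growth and fat metabolism list, miR-275 was 120-fold higher in larva (99.5 to 147), miR-8-3p 46.8-fold (37.3 to 59.6), miR-184-3p 28.9-fold (26.9 to 31.1), miR-305-3p 288-fold from 4 egg reads (112 to 1057) and miR-14-3p 394-fold from 1 egg read (70.6 to 15550). The most abundant bantam name, bantam-3p, was 7.12-fold higher (4.59 to 11.7), although the sum of bantam names was 3.67-fold lower. The other member, miR-278-3p, with 13 reads in larva and 0 in egg, was neither, but at least 4.36-fold higher by library total (lower limit 3.07). The list's median log2 ratio was 4.59, at percentile 99.8. In the miR-34 cluster, miR-34-5p (TGGCAGTGTGGTTAGCTGGTT) was 37.7-fold higher (28.7 to 50.7), miR-317 was 42-fold higher (31.6 to 57.2) and miR-277-3p, at 0 reads in egg, was at least 13.8-fold higher. That list's median was 4.92, at percentile 97.02, inside the range of random lists. Both muscle members were higher, with a median of 5.96, at percentile 96.9, also inside that range, but miR-133-5p had no shared run between the libraries, and with matching sequences alone, chosen after seeing the data, 1 member was higher.

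In the nervous system list the direction depended on the scaling. Of 7 compared members 2 were higher in larva, 2 lower and 3 neither, while by library total 6 were higher and 0 lower, and the median log2 ratio over 8 listed members, 1 of them below the minimum of reads, turned from -0.58 to 2.23. The neuronal miR-124 (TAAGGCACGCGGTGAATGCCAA) was 1.52-fold higher and not called, or 10.7-fold higher by library total. The name miR-9c-5p was 3.30-fold lower, or 2.14-fold higher by library total, and miR-263a-5p was 1.41-fold lower and not called, or 4.98-fold higher. The name miR-996-3p was 3.06-fold higher (2.62 to 3.59), and miR-7 was 8.53-fold lower, but not called by library total. For miR-1000-5p the egg library had 1 read with no shared run.

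In the let-7 complex, which is switched on at metamorphosis in Drosophila, the 3 members were lower in larva when their names were added, with a median log2 ratio of -5.03, at percentile 17.6, inside the range of random lists, and 2 were lower by library total. The fly form let-7 (TGAGGTAGTAGGTTGTATAGTA) was at 13.5 RPM in egg (11.01 to 16.3) and 39.7 in larva (35.3 to 44.4), which is 2.94-fold higher in larva by library total although its share of listed reads was lower. The top name let-7-5p was 14.2-fold lower (12.9 to 15.6), or 2.02-fold by library total. Its reads were 12.87 times those of let-7 in egg and 1.04 times in pupa, so 1234 of its 1338 egg reads were beyond those of the fly form. The egg sum of let-7 names, 5089 reads, held 104 of let-7 itself, and its call is not one of the fly form. Sequences that begin as vertebrate let-7f were at 131 RPM in egg and 41.9 in larva. The name miR-125a-5p was listed in egg and not in larva.

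In the Hox clusters 2 of 3 compared members were higher in larva and 1 neither, with miR-10-3p 8.43-fold higher (7.86 to 9.04). In the K-box family 1 of 4 was higher, 1 lower and 2 neither, against 3 higher and 1 lower by library total. The higher member was miR-2, 4.63-fold by the sum of its names, although its most abundant name, miR-2b-5p, with 101 reads in egg and 0 in larva, was at least 235-fold lower. With 1 name per member 1 was higher and 2 lower, and the list's median log2 ratio turned from 0.18 to -2.44. The name miR-13-3p was 4.204-fold higher (3.26 to 5.52), but the sum of miR-13 names was 1.28-fold higher and not called. In the miR-92 family 2 of 3 were lower and 1 neither, and the median log2 ratio over 4 listed members, 1 of them below the minimum, was -2.55 and turned to 0.27 by library total, where 1 was higher and 0 lower. With 1 name per member 1 was higher, miR-92a by 2.16-fold (1.86 to 2.52), and 2 lower. Of 2 ovary members 1 was lower and 1 neither, against 1 higher and 0 lower by library total. Both testis members compared were lower, miR-963-5p 532-fold (288 to 1114) and miR-977-5p, at 0 reads in larva, at least 41.95-fold (lower limit 30.7). The midgut miRNA miR-281 was higher, with miR-281-2-5p 67.8-fold higher from 1 egg read (12.1 to 2683). The sum of miR-281 names was 6.23-fold higher.

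Of 1155 names compared between egg and larva, 332 were higher in larva, 610 lower and 213 neither. By library total 559 were higher and 547 lower, and 18 turned from lower to higher. The share of higher names among the called was 35.2%, or 50.5% by library total. Of the called names 648 were unlisted in 1 library, and among 450 listed in both, 281 had sequences with a shared run. The largest ratios higher in larva were all of names unlisted in egg: miR-222-5p (at least 9816-fold, with a tRNA run), miR-6706-5p (6384), miR-2197 (3235), miR-2854 (2336), miR-78, miR-6317 (with an 18S rRNA run), miR-3808-3p, miR-4461, miR-5431 and miR-4078-5p (478.7). The largest ratios lower in larva were of miR-5394-5p (at least 118100-fold), miR-1683 (91950), miR-357 (31860), miR-6656-5p, miR-200b-3p, miR-4875d-3p, miR-800-5p, miR-1657, miR-4000b-5p and miR-5928d (10590), all unlisted in larva except miR-4875d-3p, which had 1 larva read with no shared run.

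**Figure D2:**
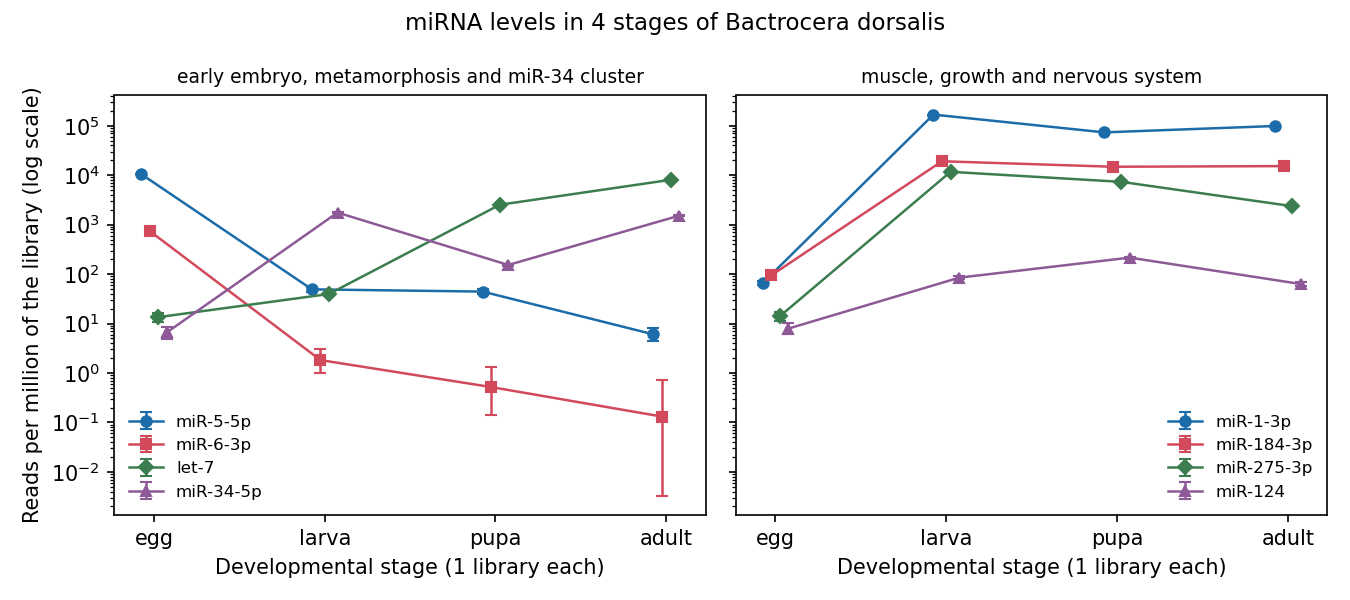
RPM of the library total on a log axis for 8 miRNAs in the 4 stages, where points are single libraries, bars are exact 95% counting intervals and lines only join the points. The name miR-5-5p, whose sequence in pupa and adult has no shared run with that in larva, is at 10560 in egg and 6.05 in adult, let-7 is at 13.5 in egg and 8069 in adult, and miR-34-5p is at 1756 in larva, 153 in pupa and 1520 in adult.

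Pupa and larva, the next pair, differed in let-7 and the miR-34 cluster. The fly form let-7 was 70.7-fold higher in pupa (63.1 to 79.4), at 2526 RPM (2490 to 2561) against 39.7. In the let-7 complex both compared members were higher, but with 1 name per member only 1 was. The median log2 ratio over all 3 listed members, of which miR-100 was below the minimum of reads, was 2.90, at percentile 99.7. In the miR-34 cluster 2 of 3 members were lower and 1 neither, with a median of -2.54, at percentile 0.51. Of 7 nervous system members 3 were higher and 4 neither, and the median over 8 listed members, 1 of them below the minimum, was 0.60, at percentile 81.4, inside the range of random lists. These counts were the same by library total.

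In these lists, let-7-5p was 33.9-fold higher (31.4 to 36.7) and miR-125b-5p, from 5 reads to 141, was 31.2-fold higher (13.1 to 97.51). The name miR-34-5p was 10.3-fold lower (9.74 to 10.98), miR-317 5.75-fold lower (5.49 to 6.01) and miR-277-3p 2.55-fold lower (2.03 to 3.22), although the sum of miR-277 names was not called. Among neuronal miRNAs, miR-1000-5p was 4.50-fold higher (4.01 to 5.05) and miR-124 2.83-fold (2.58 to 3.10). The sum of miR-9 names was 2.35-fold higher, while miR-9c-5p alone was 1.70-fold higher and not called.

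Muscle and growth miRNAs were lower or not called in pupa. The name miR-1-3p was 2.06-fold lower (2.056 to 2.069), or 2.29-fold by library total. The other muscle member, miR-133, was lower but had no shared run between the libraries. Of 7 growth members 1, bantam, was lower and 6 were neither, against 4 lower by library total, and bantam-3p alone was 1.45-fold lower and not called. The bantam call rested on the name bantam, from 422 reads to 5, which had no shared run between the libraries. With matching sequences alone, chosen after seeing the data, 0 growth members were lower. The names miR-305-3p, 2.23-fold lower (2.14 to 2.33), and miR-8-3p, 2.05-fold lower (2.003 to 2.10), were called, but the sums of their names were not. The name miR-275 was 1.44-fold lower and miR-184-3p 1.16-fold lower, neither of them called.

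In the Hox clusters 1 of 3 members was lower in pupa and 2 neither, with miR-10-3p 5.01-fold lower (4.89 to 5.12). In the miR-309 cluster 1 of 3 was lower, miR-4-3p from 11 reads to 1 (9.95-fold, 1.45 to 428), and 2 were neither. In the K-box family 1 of 3, miR-2, was higher, resting on miR-2b-5p with 14435 pupa reads and 0 in larva, and 2 were neither, while by library total 0 were called. In the miR-92 family 1 of 3 was lower, miR-312, which had no shared run, and 2 were neither. The ovary and midgut members compared were neither, but the midgut member was lower by library total. The testis name miR-963-5p, with 10 reads in larva and 0 in pupa, was at least 3.02-fold lower (lower limit 2.03).

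Of 838 names compared between larva and pupa, 243 were higher in pupa, 320 lower and 275 neither. By library total 232 were higher and 329 lower, and 0 turned direction. Of the called names 358 were unlisted in 1 library, and among 569 listed in both, 452 had sequences with a shared run. The largest ratios higher in pupa were of miR-4419b (58540-fold, 16200 to 483400, no shared run), miR-2522b-5p (at least 13380-fold), miR-2168-5p, miR-3879-5p, miR-449c, miR-2b-5p (5320), miR-3107-3p (with a tRNA run), miR-4021-3p (with an 18S rRNA run in pupa), miR-4501 and miR-139-3p. Like miR-4419b, miR-4021-3p and miR-139-3p had no shared run between the libraries. The largest lower were of miR-222-5p (at least 62080-fold, with a tRNA run), miR-6706-5p (40370), miR-78, miR-3808-3p, miR-4078-5p, miR-6006-3p, miR-2900, miR-4006b-5p, miR-542-3p and miR-548ab (1138), all unlisted in pupa. Runs of miR-6706-5p and miR-4078-5p were in the pupa list under other names. The name miR-4175-3p, with the tRNA run, was 3.51-fold higher in pupa (3.50 to 3.53), and names with a tRNA run held 15.0% of listed reads in larva and 31.7% in pupa.

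Adult and pupa, the last successive pair, differed in let-7, the miR-34 cluster and the miR-92 family. The fly form let-7 was 4.17-fold higher in adult (4.11 to 4.24), at 8069 RPM (8005 to 8133) against 2526. In the let-7 complex 2 of 3 members were higher and 1 neither, with a median log2 ratio of 2.04, at percentile 82.3, inside the range of random lists. Of the higher, miR-100 went from 4 reads to 19 by the sum of its names, which can hold the same reads. Its top name, miR-100-5p, from 3 reads to 9, was below the minimum, and with 1 name per member 1 was higher. In the miR-34 cluster 2 of 3 were higher and 1 neither, with a median of 1.91, at percentile 98.1. All 3 compared miR-92 family members were lower, and the median over 5 listed members, 2 of them below the minimum of reads, was -2.79, at percentile 0.89. These directions were the same by library total.

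In these lists, miR-34-5p was 12.97-fold higher (12.2 to 13.8), miR-277-3p 20.8-fold higher (17.0 to 25.6) and miR-317 1.39-fold higher and not called. The sum of miR-277 names was 3.75-fold higher. The name let-7-5p was 4.18-fold higher (4.11 to 4.24). In the miR-92 family, miR-92a was 27.7-fold lower (22.7 to 34.1), miR-310 9.05-fold lower (6.52 to 12.9) and miR-312 had no shared run. The sum of miR-92 names was 11.3-fold lower and that of miR-310 names 6.92-fold lower. With matching sequences alone, a setting chosen after seeing the data, 2 members were lower and the median over all listed members turned to 0.0231. That median includes the 2 members below the minimum, which entered as higher. For miR-311, from 2 reads to 0, the 1.98-fold rise comes from the floor of 3 reads, and miR-313 went from 3 reads to 5.

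Some neuronal miRNAs that were higher in pupa than in larva were lower in adult than in pupa. The name miR-124 was 2.62-fold lower (2.36 to 2.90) and miR-1000-5p 5.16-fold lower (4.48 to 5.96). The sum of miR-9 names was 4.82-fold lower. In all, 3 of 7 nervous system members were lower, 1 was higher and 3 neither, against 4 lower and 0 higher by library total. The median log2 ratio over 8 listed members, 1 of them below the minimum, was -0.61, at percentile 23.4, inside the range of random lists. The higher one was miR-7, at 3.17-fold for the name alone (2.46 to 4.11). Of 7 growth members 1 was higher, 2 lower and 4 neither, with miR-275 2.39-fold lower (2.35 to 2.43), miR-305-3p 2.04-fold lower (1.91 to 2.18) and miR-278-3p 3.47-fold higher from 8 reads to 21 (1.48 to 9.05). The name miR-1-3p was 1.76-fold higher and not called.

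In the Hox clusters 2 of 3 members were higher in adult and 1 lower, with miR-993-3p 3.63-fold higher (2.88 to 4.60), miR-10-3p 2.24-fold higher but not called by library total, and miR-iab-4-5p 7.57-fold lower (4.45 to 13.9). In the K-box family 2 of 3 were lower and 1 neither, with miR-13-3p 2.41-fold lower (2.18 to 2.68). In the miR-309 cluster 1 of 2 was lower, miR-5-5p by 5.61-fold (4.12 to 7.81), and 1 neither, against 2 lower by library total. The ovary member miR-989 was neither by the sum of its names, although miR-989b alone was 14.6-fold lower (9.53 to 23.6). The midgut member was higher by sum and not called by library total. No testis member was listed in either library.

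Of 896 names compared between pupa and adult, 423 were higher in adult, 261 lower and 212 neither. By library total 401 were higher and 290 lower, and 0 turned direction. Of the called names 416 were unlisted in 1 library, and among 563 listed in both, 422 had sequences with a shared run. The largest ratios higher in adult were of miR-765 (at least 50360-fold), miR-6127 (36460), miR-2253a (23140-fold from 1 read, 4152 to 913900, no shared run), miR-4956-3p (no shared run), miR-3186-5p, miR-6244, miR-328a-5p, miR-4430, miR-3173 and miR-1844 (4560). Of these miR-328a-5p, miR-3173 and miR-1844 carried a run of bacterial rRNA. In adult 9 names with such a run held 2.87% of listed reads, and in pupa 3 names held 0.0295%. The largest lower were of miR-4419b (16030-fold, 6870 to 49380, no shared run), miR-2197 (at least 11850-fold), miR-2522b-5p (9158), miR-6317 (with an 18S rRNA run), miR-4501 (no shared run), miR-449c, miR-2b-5p, miR-3107-3p (with a tRNA run), miR-5890e (a run of it is in adult under another name) and miR-4021-3p (with an 18S rRNA run).

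For the other pairs, 304 names were higher in pupa than in egg and 610 lower, of 1075 compared, against 475 higher and 555 lower by library total. In adult 417 were higher than in egg and 603 lower, of 1191, against 590 higher and 543 lower by library total. The shares of higher names among the called were 33.3% and 40.9%, or 46.1% and 52.1% by library total. In adult 405 were higher than in larva and 324 lower, of 972, against 380 higher and 368 lower by library total. The fly form let-7 was 295-fold higher in adult than in larva (263 to 331) and 123-fold higher than in egg (102 to 151).

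**Figure D3:**
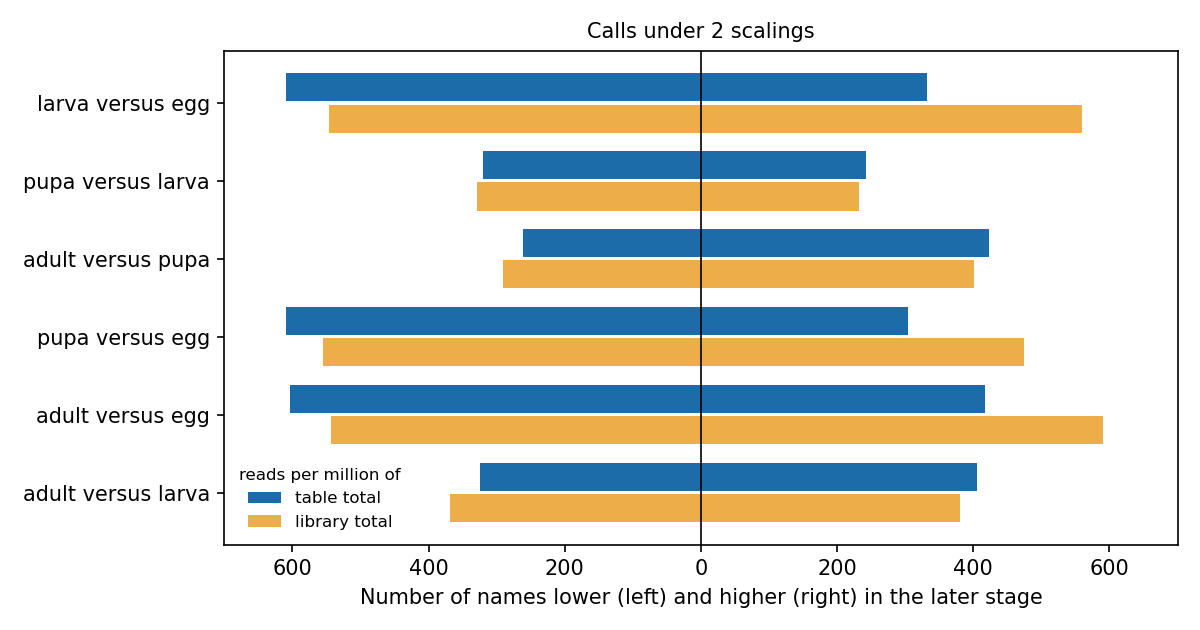
Number of names called lower (left) and higher (right) in the later stage for the 6 pairs, by share of listed reads and by library total. For larva versus egg 332 names are higher by listed reads and 559 by library total, and for pupa versus larva 243 and 232.

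Names seen in 1 stage alone were most numerous in egg. With 10 or more reads in 1 library and 0 in the other 3, there were 308 names in egg, 124 in larva, 76 in pupa and 160 in adult, holding 40.6%, 12.8%, 4.15% and 16.9% of listed reads. For 302, 111, 72 and 154 of them no other library held a run of 16 bases of the sequence under any name. A count of 0 allows up to 3 reads.

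Larva, pupa and adult profiles were more alike than any was to egg. Across 2385 names, which are not independent replicates, Spearman's rho was 0.41 between larva and pupa (0.37 to 0.45), 0.37 between pupa and adult (0.33 to 0.41) and 0.32 between larva and adult (0.27 to 0.36). With egg it was -0.05 for larva (-0.09 to -0.01), 0.03 for pupa (-0.0077 to 0.0762) and -0.06 for adult (-0.10 to -0.03), and for pupa its sign turned among names with 10 or more reads (-0.0484).

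Of 177 precursor names with both arms listed, 44 had 10 or more reads in every library, and for 7 the dominant arm differed between libraries. These were let-7, miR-13, miR-2b, miR-4094, miR-79, miR-932 and miR-9b. Among the 30 precursors whose arms had no differing sequences between libraries, 2 differed, miR-13 and miR-932, while in the other 5 an arm held sequences with no shared run. For miR-932 each arm kept a shared run across the 4 libraries. The 5p arm of miR-13 was listed in egg alone, so its sequence could not be compared. The 5p share of miR-13 was 82.1% of 340 reads in egg (77.6 to 85.99) and 0% in larva, pupa and adult, with upper limits of 0.2055%, 0.2405% and 0.764%. That of miR-932 was 35.7% of 56 reads in pupa (23.4 to 49.6) and 73.0% of 189 in adult (66.1 to 79.2).

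Of the fixed markers of other organisms, 0 of 6 plant names and 7 of 7 vertebrate names were listed. The plant names were sought without a hyphen and every listed miR name has one. Their absence therefore does not tell whether plant miRNAs were present. A listed name need not carry the vertebrate sequence. That of miR-451 had 0 reads in every library, and that of miR-16 had 1 read, in larva. The names miR-206-3p and miR-21-5p carried the vertebrate sequence in every library. The muscle miRNA miR-206-3p was at 98.2 RPM in egg (91.3 to 105.4), 91.6 in larva (84.9 to 98.6), 74.5 in pupa (68.5 to 80.8) and 62.6 in adult (57.1 to 68.5). The name miR-21-5p was at 16.6, 7.31, 7.54 and 5.79 RPM. The name miR-122-5p, at 140.8 RPM in pupa, had a vertebrate sequence in 0 libraries.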

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

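The settings with matching sequences, and library totals for lists, were chosen after seeing the data. With library totals, names higher were 559 for larva versus egg and 475 for pupa versus egg, because that denominator multiplies every ratio with egg. With a minimum of 100 reads fewer names were compared: lower names were 247 for larva versus egg, 238 for pupa versus egg and 246 for adult versus egg. Higher names were then 265, 264 and 328, so the balance turned. The excess of lower names by the main rule lay in names below that minimum, where the higher floor in egg limits calls of higher names. The shares of higher names among the called were 51.8%, 52.6% and 57.1%, against 35.2%, 33.3% and 40.9% by the main rule. That minimum gave 141 higher and 150 lower for pupa versus larva, 241 higher for adult versus pupa, and 228 higher and 173 lower for adult versus larva. With names added per miRNA, which can count reads more than once, the leading share was 38.8% in larva and 33.5% in adult, and the 10 leading held 79.1% in larva, 73.5% in pupa and 71.4% in adult. Names seen in 1 stage alone were 110, 47, 45 and 87 for egg, larva, pupa and adult with a minimum of 100 reads. For larva they were 199 with a minimum of 3 and 60 with counts thinned to 479166 reads. With 10 or more reads rho was -0.12 for egg and larva, -0.18 for egg and adult and 0.49 for larva and pupa, and for egg and pupa it turned to -0.0484. With 100 or more it was -0.0815 for egg and pupa, also turned, -0.22 for egg and adult, 0.51 for larva and pupa and 0.30 for pupa and adult. List members higher in larva than in egg were 26 and lower 10 with library totals, against 16 and 17 by listed reads. Members lower in pupa than in larva were 14 under median-of-ratios factors and 14 without the 5 most abundant names, against 9. The miR-92 family's median for adult versus pupa turned from -2.79 to 0.0231 with matching sequences, where 2 members below the minimum of reads entered as higher. For rho and the lists the cause was not tested.

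Of the recomputed values that answer a comparison, 186 stayed within 1.5 times a count or within the interval of a value, 31 moved and 2 reversed. Of 244 recomputed medians of single lists, 218 moved by no more than the SD of the list's members (0.5 for a list of 1 member), 25 moved further and 1, the miR-92 family above, turned from outside the range of random lists. Whatever their size, 14 of the 244 had the other sign, in 7 pairs of a list and a comparison. No paired analysis was possible because each stage has 1 library. The pseudocounts chosen beforehand were not run, since they applied only to a table without counts. A count of 0 cannot be told from 3 reads or fewer at this depth.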

Other observations

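The miRNAs in the next paragraph were chosen after their values were seen. The tests of miscalled bases and of tRNA and rRNA sequence were chosen after the result was seen.

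Conserved insect miRNAs outside the fixed lists also differed between stages. The name miR-375-3p, known from endocrine cells of vertebrates, was at 0.648 RPM in egg, 982 in larva, 217 in pupa and 131 in adult. It was 215-fold higher in larva than in egg, from 5 egg reads (92.2 to 663). The name miR-31a-5p was at 2.98 RPM in egg, 2360 in larva, 1840 in pupa and 1786 in adult, and miR-276a-3p at 2.20, 3635, 4013 and 3908. The name miR-210-3p, known from photoreceptors of Drosophila, was at 2.09 RPM in larva, 14.7 in pupa and 150 in adult, and was 13.3-fold higher in adult than in pupa (10.98 to 16.3). In egg it had 1 read, with no shared run.

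Vertebrate miRNA sequences were listed in all 4 libraries, such as that of miR-206-3p at 98.2 RPM in egg and 62.6 in adult. Miscalled bases of the fly's own miRNAs would keep a fixed ratio to them, but the ratio of miR-206-3p to miR-1-3p differed 2749-fold between libraries and that of let-7f-5p to let-7-5p 173-fold. The name let-7-5p holds reads beyond the fly form. Against let-7 itself, with 104 reads in egg and 61369 in adult, let-7f-5p had 1012 and 279. Reads from a vertebrate sample may account for these sequences, and this stays open. Of 36 vertebrate sequences not looked at before, 7 had 10 or more reads, and their median highest-to-lowest ratio was 4.35, between the bounds of 4 and 10 set in advance. Each of these 7 was highest in egg, such as miR-29a at 21.1 RPM in egg and 4.73 in adult. Among sequences looked at before, let-7c was instead highest in adult, at 52.7 RPM against 10.75 in egg. This shared direction was seen afterwards and does not settle the source. For the members of the fixed insect lists the median was 47.2. The 2 medians are not at like depth. The insect member miR-1-3p had up to 1290611 reads, while the vertebrate miR-191 had at most 16. With so few reads, a count of 0 set to 3 limits the ratio. No biological explanation was tested.

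Fragments of tRNAs and of bacterial rRNA may have been counted under miRNA names. The first test, a pattern of tRNA boxes, found 12 pupa sequences against at most 11 in 100 shuffles, a narrow margin, 14 in larva against 10 and 17 in adult against 12, while in egg its 9 did not exceed the highest shuffle, 10. Runs of 12 bases, tried after that result with sequences and run length chosen on these data, were in 11 pupa sequences against at most 2 in shuffles. Runs of bacterial rRNA, chosen in the same way, were in 9 adult sequences against at most 3. Where such bacteria came from, and a stage difference in tRNA cleavage, were not tested.

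Many names had sequences with no shared run in different libraries. If 1 name covers unrelated reads, its counts in larva and pupa should be unrelated. Spearman's rho across 117 such names was 0.257 (bootstrap range 0.0796 to 0.431), below the bound set in advance, although the range crosses it. Across 452 names with a shared run rho was 0.92. Names that stand for unrelated reads would give such a result, but the 117 names also hold close variants. One is miR-5-5p, with 377 reads in larva and 341 in pupa. Some have few reads, such as miR-139-3p with 1 in larva. The result therefore does not show that a given name holds unrelated reads. The matching rule behind the names is not given in the sources used here.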
